A study of Mus musculus with 10 samples.

How the data were processed

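Total RNA and ribosome footprints were measured in cerebellum of Bmal1 knockout and wild-type littermate mice. Bmal1, whose gene symbol is Arntl, is a transcription factor of the circadian clock. Per the labels' protocols, the mice came from crosses of heterozygous parents on a C57BL/6 background and lived in 12 h of light and 12 h of dark. Frozen cerebellum was lysed with cycloheximide, which stalls ribosomes. Part of each lysate was digested with RNase I, so that only RNA covered by ribosomes was left, and fragments of 28 to 34 nt were kept as footprints. The rest was kept as total RNA and fragmented for 40 min. Ribosomal RNA was depleted from all samples. The labels give neither the sex of the mice nor the time of day at which tissue was taken.

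The series has 10 libraries, and the table of values has a column for 8 of them: footprints and total RNA of knockout animals 1 and 3 and of wild-type animals 2 and 3. Total RNA of knockout 2 and of wild type 1 has no column and was not analysed here. The design had been written for 3 against 3 total RNA libraries and 10 libraries in the test of translational efficiency. The comparisons were therefore 2 against 2 for total RNA, 2 against 2 for footprints, and 8 libraries for translational efficiency.

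Per the submitters' processing notes, Bowtie, STAR and Cufflinks were used with the mouse build mm10. The notes give no versions, settings or roles for these tools. The authors' values per library are RPKM, reads scaled by a length and by the library's depth, per the file headers. A second table by the authors holds translational efficiency as a ratio. This ratio was checked in 57412 values, leaving out those with low footprint or total RNA RPKM. All of these equalled footprint RPKM over total RNA RPKM of the same animal within 2%. The ratio is listed as 0 for 1222 values with footprints above 0 and total RNA at 0. Both tables carry a mean read count per gene by the authors. With the relative depths of the libraries, which are visible in the steps between low values, this column is the geometric mean of the 8 read counts: of 4392 values of genes with a mean under 20, 99.93% fell within 0.1 of a whole number, against 19.4% for an arithmetic mean.

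Whole reads per gene and library were recovered in this way for the 13880 genes above 0 in all libraries. The recovered total RNA libraries held 25.6 M to 43.2 M reads and the footprint libraries 27.7 M to 41.0 M. The table has 22046 protein-coding genes, of which 4106 were listed at 0 in every library. Of its gene IDs, 22028 were found in GENCODE M21, which uses the same build, and 96.5% of those had the same span. The factor between RPKM and reads differed between genes (5th percentile 3.81 reads per RPKM, median 47.8, 95th percentile 304) and had no rank correlation with coding length, exon length or gene span (Spearman rho 0.0 each). RPKM is therefore compared here only within a gene and never between genes, and a pseudocount or filter on RPKM acts at different read depths in different genes. Ratios of RPKM within a gene do not depend on that factor, while log2 fold changes with a pseudocount do where RPKM is low. Rankings of genes and cut-offs by log2 fold change therefore depend on it for such genes. Genes with near-identical copies, such as Gapdh, Ubb and most ribosomal protein genes, and several mitochondrial genes listed at 0, are uncertain, since the counting rule is not stated. Replicates were not copies of each other: chi-square over its degrees of freedom between the libraries of a group lay between 12.7 and 41.3.

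Differences between genotypes were computed with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a variance trend, for genes with a mean RPKM of at least 1 in the libraries compared. Translational efficiency was tested as the interaction of genotype and kind of library, in genes passing that filter in both kinds. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and "called" means past it. Log2 fold changes are knockout minus wild type, given with the standard error (SE) from limma. RPKM is given as mean ± SD of 2 animals. Every adjusted p of a gene is limma's, and limma's camera, with a preset correlation between genes of 0.01, tested 28 gene lists that have at least 5 tested genes. The lists hold clock genes bound by the BMAL1 complex at E-box motifs, other clock genes, mTORC1 pathway genes, ribosomal protein genes, other TOP mRNAs, initiation factors, nuclear respiratory chain genes, mitochondrially encoded genes, ion channels, synapse genes and genes recurrently mutated in autism. They further hold markers of Purkinje cells, granule neurons, interneurons, astrocytes and Bergmann glia, oligodendrocytes, microglia, reactive glia, endothelial and mural cells, choroid plexus, meninges, neighbouring brainstem and midbrain, and blood. The rest are immediate early, antioxidant, integrated stress response, heat shock and cold, and glucocorticoid-induced genes. List tests were repeated with an estimated correlation and with fry. The correlation of fold changes between kinds of library is across genes, which are not independent replicates.

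The lists, tests, alternatives and rule for naming genes were fixed before the data were examined. The rule names Arntl, the 10 called genes with the largest increase and the 10 with the largest decrease per comparison (or, with fewer than 10 calls, the 10 smallest unadjusted p), all measured E-box clock genes, and up to 4 members of each other list: called members by size, or else the 2 with the smallest unadjusted p. The text gives the few that matter and counts for the rest. Alternatives were other pseudocounts and filters, median centring, quantile normalization, no variance trend, all libraries in one fit, a block by animal, and leaving out each library. After the values had been seen, limma-voom on the recovered reads was added, with library sizes from totals or from median ratios. Footprint and total RNA libraries of one animal come from one lysate, per the labels' protocols, so that the animal pairs them. The correlation of their deviations from the group means was -0.004 in the knockout and 0.246 in the wild type. It runs over genes with a mean RPKM of at least 1 across all libraries. The like correlation in the Results runs over the genes tested in both kinds. Between genotypes only number 3 is shared.

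The tests were tried on simulated reads drawn from the real means and depths, with negative binomial spread between animals that was the same for all genes of a kind of library (dispersion 0.00451 for total RNA and 0.0127 for footprints). That spread was a median over genes with many reads. The rates below hold for genes with that spread and can be too high for genes that vary more. In the real footprints Nr1d1 (-2.55, adjusted p = 0.0788) and Per3 (-2.36, 0.0794) were not called. In the real efficiency test several genes changed by over 2 log2 units were not called either, as given in the Results. For total RNA, limma called 100% of 45 genes lowered by 1 log2 unit and 97.8% of 45 raised by 1, with 20 calls among 12211 unchanged genes. For footprints it called 97.6% of 41 and 95.6% of 45, with 21 calls among 12070. For translational efficiency it called 75.6% of 45 each way, with 7 calls among 11780. Limma called all simulated genes changed by 2 log2 units in each comparison. In total RNA and footprints, though not in efficiency, calls among unchanged genes made up more of limma's simulated calls than the threshold allows. Calls in the real total RNA and footprints may hold a like excess. Limma-voom on simulated reads gave 10 calls among 13664 unchanged genes for total RNA and 10 among 13665 for footprints. Of 50 genes changed by 1 log2 unit each way, it called 94% and 88%. A planted list of genes raised by 0.5 log2 units was found by camera with the preset correlation, with adjusted p 1.92e-32 for total RNA, 3.12e-16 for footprints and 3.98e-08 for translational efficiency. With an estimated correlation it was missed, with adjusted p 0.159, 0.32 and 0.208. By fry it was found in total RNA (adjusted p = 0.0115) and missed in footprints (0.0818) and efficiency (0.0658). In efficiency fry also called 1 of 27 lists of unmoved genes. Simulated genes were drawn independently of each other, while choroid plexus markers had an estimated correlation of 0.737 in total RNA and 0.973 in footprints. The simulation therefore cannot tell whether the preset correlation suits such lists. Tables and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and the block by animal as a random effect used statmod 1.5.0.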

Results

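The study asked what the loss of Bmal1 does to gene expression and to translation in the cerebellum, in a mouse with autism-like behaviour and a link to mTORC1, the kinase complex that controls protein synthesis. Total RNA and ribosome footprints were compared between 2 knockout and 2 wild-type animals. Knockout total RNA had 38.9 M and 43.2 M recovered reads, wild-type total RNA 25.6 M and 27.8 M, knockout footprints 41.0 M and 30.1 M, and wild-type footprints 38.1 M and 27.7 M. Both knockout total RNA libraries were deeper than both wild-type ones, so that depth and genotype go together in total RNA. This limits the reading of genes listed at 0 in the wild type.

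The targeted gene, Arntl (ENSMUSG00000055116; mm10 chromosome 7, 113207465 to 113314126), had more total RNA and fewer footprints in the knockout. Its total RNA was 269.8 ± 3.40 RPKM (SD, n = 2) in the knockout and 179.1 ± 0.398 in the wild type, a log2 fold change of 0.59 (SE 0.08, adjusted p = 0.0158). Its footprints were 115.3 ± 11.9 RPKM in the knockout and 276.1 ± 26.2 in the wild type, a log2 fold change of -1.25 (SE 0.14) that missed the threshold (adjusted p = 0.0589; limma-voom adjusted p = 0.00172). The ratio of footprints to total RNA was 0.463 and 0.393 in the knockout animals and 1.44 and 1.64 in the wild-type animals. The difference in efficiency, -1.84 log2 units (SE 0.15), was called (adjusted p = 0.0367). The labels do not say which part of the gene is deleted, so the total RNA value does not check the genotype of an animal, while the footprints separated the genotypes in both pairs of animals. Without knockout 1 or knockout 3 the total RNA call was lost (adjusted p = 0.11 and 0.0897), as it was with no filter (0.0641), and without any one of the 4 animals the efficiency call was lost (adjusted p 0.223 to 0.658). It was also lost with the animal as a fixed block, which respects that both libraries of an animal come from one lysate (0.132), with no filter (0.0577), with quantile normalization (0.0566) and without a variance trend (0.0729).

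**Figure D1:**
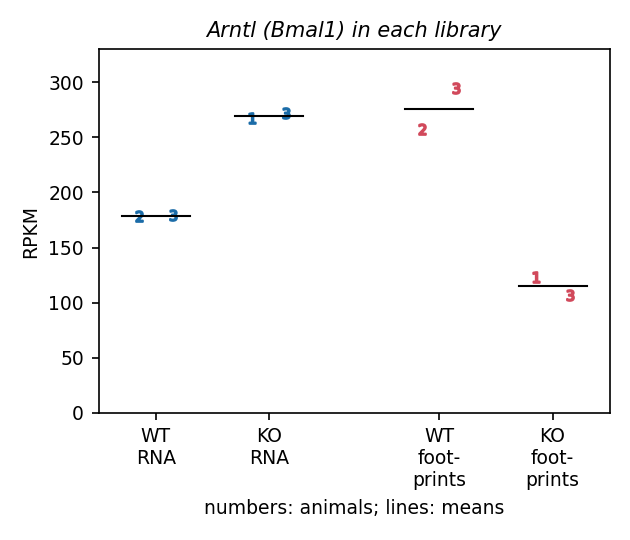
RPKM of Arntl in each of the 8 libraries, on a linear axis from 0. Each digit is an animal's number and lines are group means (n = 2): knockout total RNA (mean 269.8) lies above wild-type total RNA (179.1), and knockout footprints (115.3) lie below wild-type footprints (276.1).

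In total RNA, 12 of the 15 clock genes that BMAL1 drives through E-box motifs fell in the knockout, and the largest increases were led by genes outside the clock. Spon2 (ENSMUSG00000037379, chromosome 5, 33198184 to 33218455), which encodes a secreted matrix protein, rose from 0.649 ± 0.222 to 151.2 ± 7.84 RPKM, a log2 fold change of 6.53 (SE 0.13, adjusted p = 3.41e-05). Fabp7 (ENSMUSG00000019874, chromosome 10, 57784881 to 57788450), a fatty acid binding protein of astrocytes and Bergmann glia, rose from 17.3 ± 0.965 to 246.5 ± 3.07 RPKM (3.76, SE 0.09, adjusted p = 5.62e-05). Npas2, a paralog of the BMAL1 partner CLOCK, rose from 0.495 ± 0.0832 to 10.6 ± 1.33 RPKM (2.95, SE 0.14, adjusted p = 0.00127). Nr1d2 (ENSMUSG00000021775, chromosome 14, 18204054 to 18239127), which encodes the clock repressor REV-ERB beta, fell from 26.6 ± 0.172 to 1.89 ± 0.0456 RPKM (-3.26, SE 0.10, adjusted p = 0.000227).

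Of 12690 genes tested in total RNA, 519 were called (4.09%), 315 higher and 204 lower in the knockout, and 158 of them changed by at least 1 log2 unit. By limma 2810 of the 12690 genes had an unadjusted p under 0.05. Counts at that level within gene lists of total RNA are to be read against this background. The other large increases were in C2cd4b (3.63), Prlr (3.18), the monocarboxylate transporter gene Slc5a8 (3.08), Rhbdl2 (2.70), Gucy2f (2.42) and Cnksr1 (2.40). Ptf1a, a transcription factor gene of cerebellar GABAergic neuron development, was listed at 0 in the wild type and at 4.28 ± 0.321 RPKM in the knockout (adjusted p = 0.0018). The other large decreases were in the interferon-induced gene Ifit3b (-2.98), Etnppl (-2.63), which encodes a phospholyase of astrocytes, Tcap (-2.61), Per3 (-2.52), the heparan sulfatase gene Sulf1 (-2.18), Ccdc73 (-1.99), Nr1d1 (-1.96), the RNA-binding protein gene Rbm24 (-1.90) and Dbp (-1.85). In all 519 called genes both knockout libraries lay on one side of both wild-type libraries, which a call at 2 against 2 libraries all but requires, as in 53.1% of the genes not called and in 33.3% by chance. Prlr was not called without knockout 1 or knockout 3. Ccdc73 was not called without either wild-type animal, and Tcap was not without wild type 2. The count was 117 without knockout 1, 172 without knockout 3 and 299 without wild type 2, and 26 with no filter on low values, 217 with all libraries in one fit and 798 among genes with a mean read count of at least 100. By limma-voom 1684 genes were called, 816 higher and 868 lower. Of the 519 genes called by limma, 491 had recovered reads, and 453 of these were among the 1684.

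Of the 15 E-box clock genes, 12 fell, Cry1 rose and 2 were not called, and all 15 passed when adjusted over the list alone. Nr1d1, the gene of the repressor REV-ERB alpha, fell from 111.7 ± 6.74 to 28.1 ± 2.82 RPKM (-1.96, SE 0.11, adjusted p = 0.0018), and Dbp, an output transcription factor of the clock, from 17.0 ± 0.874 to 3.99 ± 0.0874 (-1.85, SE 0.11, adjusted p = 0.0018). The period genes fell as well: Per3 by a log2 fold change of -2.52, Per2 by -1.37 and Per1 by -0.87. Ciart (-1.84), Tef (-1.11), Bhlhe40 (-0.85), Wee1 (-0.80), Hlf (-0.69) and Bhlhe41 (-0.63) fell with them. Cry1, a cryptochrome gene, rose from 196.9 to 403.8 RPKM (1.03, SE 0.11, adjusted p = 0.00964), while Cry2 (0.40, adjusted p = 0.0695) and Usp2 (-0.46, adjusted p = 0.0865) were not called. The list was called lower by camera (adjusted p = 2.66e-10), with adjusted p = 0.593 under an estimated correlation and 0.00785 by fry. Of the 13 called genes, 10 still passed without knockout 1, 8 without knockout 3, 8 without wild type 2 and 11 without wild type 3, and those that did not were among Bhlhe40, Bhlhe41, Hlf, Per1, Per2 and Wee1. Among 12 other clock genes, Npas2, Nfil3 (1.21), which represses targets of Dbp, and Clock (0.69) rose and Arntl2 (-1.18), the paralog of Arntl, fell. That list was not called by camera (adjusted p = 0.209, and 0.0334 by fry and 0.0339 on the limma-voom fit), and Clock was not called without knockout 1 (adjusted p = 0.107) or knockout 3 (0.0691).

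**Figure D2:**
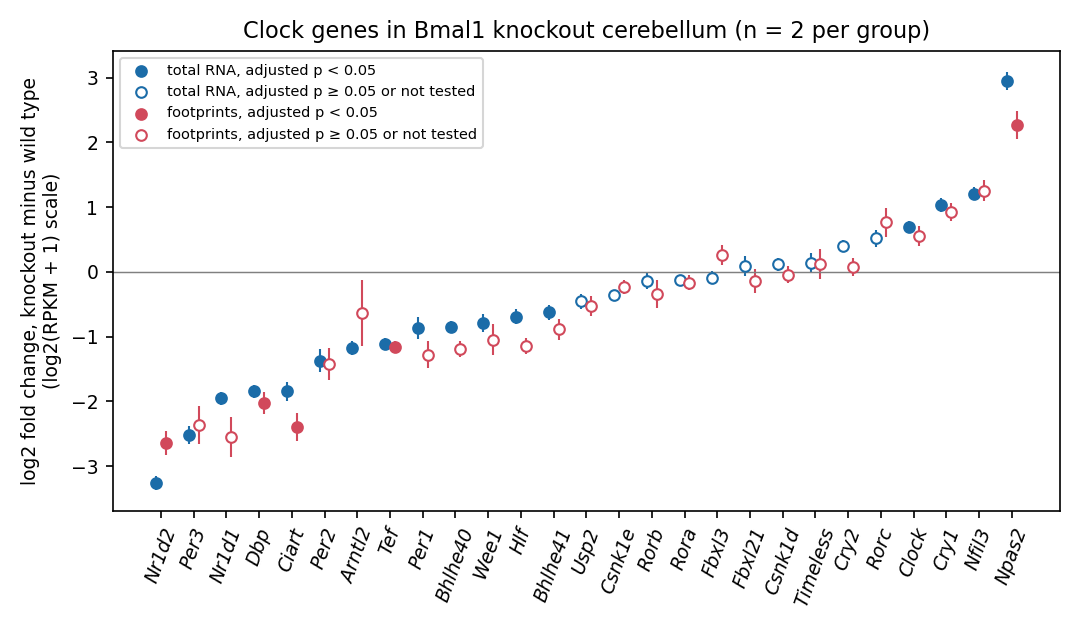
Log2 fold change, knockout minus wild type, of the E-box and other clock genes in total RNA (blue) and footprints (red), with the standard error from limma (n = 2 per group). Filled points passed the threshold: values run from -3.26 (Nr1d2) to 2.95 (Npas2) in total RNA.

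Markers of several cell types moved in total RNA. Granule neuron markers were called higher as a list (camera adjusted p = 0.00245, and 0.593 with an estimated correlation): Grin2c (0.73), an NMDA receptor subunit gene, Fat2 (0.55) and Tiam1 (0.39) rose, and 13 of 16 were not called (5 passed over the list alone). Microglia markers were called lower (adjusted p = 1.27e-04, and 0.593 with an estimated correlation): the complement gene C1qb (-0.57) and the protease gene Ctss (-0.53) fell, and all 12 tested members had a negative fold change (6 passed over the list alone). By fry neither the granule nor the microglia list was called (adjusted p = 0.204 and 0.0615). Among 15 astrocyte and Bergmann glia markers Fabp7 rose and S100b (-0.65) fell (list adjusted p = 0.209, and 0.00785 by fry). None of 18 Purkinje cell markers was called by limma (list adjusted p = 0.371; 1 gene at unadjusted p under 0.05 and 1 by limma-voom), with Calb1 at -0.21 and Lhx1 at 0.28. Of 17 oligodendrocyte markers Mag (-0.39) fell (adjusted p = 0.06), of 14 interneuron markers Eomes (-0.91) fell (0.0627), and of 14 endothelial and mural markers Cldn5 (0.84) rose (0.711). Among 11 meningeal markers Igfbp2 (1.07) rose and Dcn (-0.82) fell (0.711), and the list of 6 blood genes was not called (0.443). Of the reactive glia genes Vim (-0.74) fell, and too few were tested for a test of the list. The list calls of granule and microglia markers held without each library. On the limma-voom fit the oligodendrocyte list (0.0037) and the interneuron list (0.0137) were called lower. With 1 library left out, the oligodendrocyte list was called lower without knockout 3 or wild type 3. It was not called without knockout 1 or wild type 2. The interneuron list was called lower without knockout 1 or wild type 3, and not without knockout 3 or wild type 2. Wild type 2 also stood apart in brainstem genes, as given below. Of the calls of genes named in this paragraph that of Fabp7 was kept without knockout 1, those of Fabp7, Igfbp2 and Dcn without knockout 3, those of Fabp7, S100b, Cldn5, Igfbp2, Dcn and Vim without wild type 2, and all but those of C1qb and Mag without wild type 3.

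Choroid plexus markers, genes of the epithelium that makes cerebrospinal fluid, were called higher (camera adjusted p = 1.64e-05, and 0.593 with an estimated correlation). By fry the list was not called (adjusted p = 0.236). Of 9 tested members Prlr (3.18, adjusted p = 0.0397) and Sostdc1 (1.61, adjusted p = 0.0207) rose, and 8 passed over the list alone. The wild-type animals differed widely in these genes: Ttr, the transthyretin gene, was at 11753 and 13916 RPKM in the knockout, 5390 in wild type 2 and 208.4 in wild type 3, and Kl was at 577.7, 599.7, 277.0 and 37.2. Without knockout 1 or knockout 3 neither gene was called, while the list was without each library. Brainstem and midbrain genes were not called as a list (adjusted p = 0.192), with Tph2 (0.89) higher and Slc17a6 (-0.56) lower of 9. Wild type 2 stood apart in them, with Hoxa5 at 40.6 RPKM against 0.727 in wild type 3, 1.40 in knockout 1 and 1.57 in knockout 3. The brainstem list rests on that animal: it was called lower without wild type 3 (adjusted p = 2.57e-05), and without wild type 2, with 5 genes tested, its direction turned (adjusted p = 0.939). Tph2 and Slc17a6 were called without wild type 3 and not without any of the other animals.

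**Figure D3:**
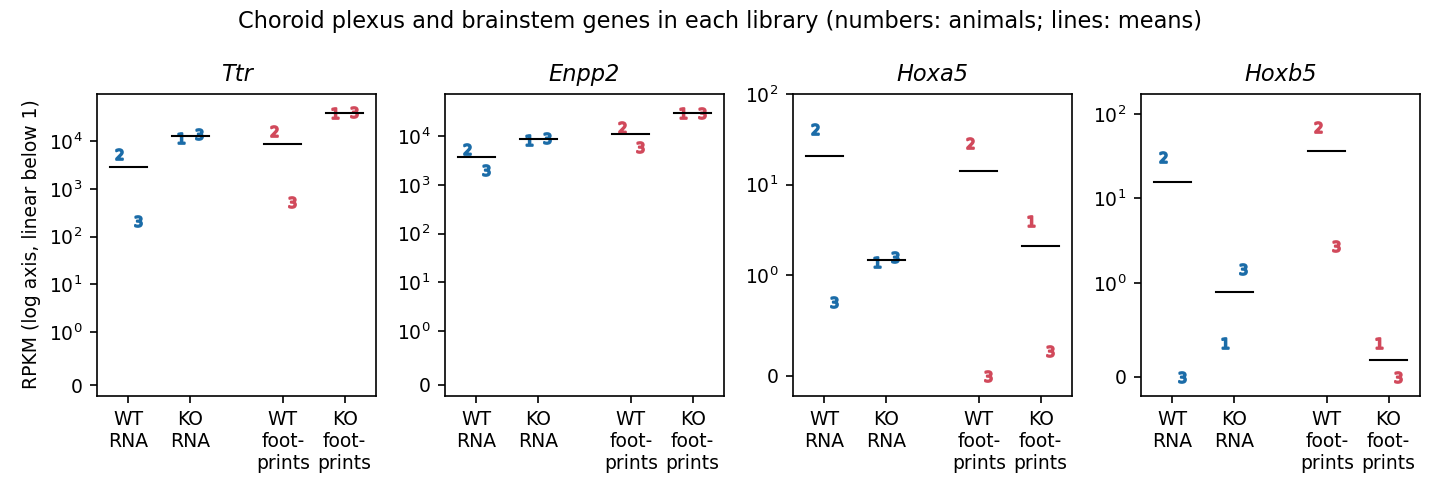
RPKM of the choroid plexus genes Ttr and Enpp2 and of the brainstem genes Hoxa5 and Hoxb5 in each library, on a log axis that is linear below 1. Digits are animal numbers and lines are group means (n = 2): in total RNA, wild type 3 had 208.4 RPKM of Ttr against 5390 in wild type 2, and wild type 2 had 40.6 RPKM of Hoxa5 against 0.727 in wild type 3.

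The other lists called in total RNA were heat shock and cold genes, glucocorticoid-induced genes and ion channels, each with adjusted p = 0.593 under an estimated correlation. By fry none of them was called (adjusted p = 0.153, 0.0694 and 0.148). Of 13 heat shock and cold genes Hspa1a (-1.07), a stress-induced chaperone gene, fell (list lower, adjusted p = 0.00206, 3 over the list alone). Of 11 glucocorticoid-induced genes the lipid droplet gene Plin4 (-1.65), Zbtb16 (-1.40) and Tsc22d3 (-0.79) fell and Cdkn1a (2.23), which encodes the cell cycle inhibitor p21, rose (list lower, adjusted p = 0.0139, 7 over the list alone). Of 24 ion channel genes the potassium channel gene Kcna2 (0.79) and the calcium channel gene Cacna1e (0.48) rose and the sodium channel gene Scn1a (-0.46) fell (list higher, adjusted p = 0.0316, median 0.11, 4 over the list alone), in libraries in which granule neuron markers were higher too (median 0.18). The ion channel list was not called without knockout 1 (adjusted p = 0.0825) or without wild type 3 (0.092). Of the single-gene calls those of Hspa1a, Cacna1e and Scn1a were lost without knockout 1, knockout 3 or wild type 2, that of Zbtb16 without knockout 1 or wild type 2, and that of Tsc22d3 without knockout 1.

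Lists close to the study's questions were not called in total RNA with all libraries, and several were near the threshold. The autism, synapse and respiratory chain lists were called without knockout 3 (adjusted p = 0.0115, 0.0233 and 0.0488), without wild type 2 (0.00392, 0.0219 and 0.00392) and on the limma-voom fit (0.0419, 0.0339 and 0.0419), the first 2 higher and the last lower. Ribosomal protein genes were called lower without wild type 2 (0.0415), mitochondrially encoded genes lower without wild type 3 (0.0104) and immediate early genes higher without knockout 1 (0.0288). Of 45 mTORC1 pathway genes 1 fell, Tfeb, which encodes a lysosomal transcription factor that mTORC1 controls, from 162.3 ± 20.2 to 105.1 ± 9.26 RPKM (-0.62, adjusted p = 0.0476), and 2 passed over the list alone (list adjusted p = 0.33). By limma-voom 3 mTORC1 pathway genes were called higher and 2 lower in total RNA, 6 and 2 of the autism genes, 8 and 3 of the synapse genes, and 0 and 4 of the ribosomal protein genes. Of 34 genes recurrently mutated in autism the neurexin gene Nrxn2 (0.49) rose (list adjusted p = 0.0602). Of 30 synapse genes Syt1 (0.58), Camk4 (0.40) and Syt2 (0.33) rose and Slc17a6 (-0.56) fell (0.0627). Of 68 ribosomal protein genes Rpl29 (0.79) rose (0.19), a family whose reads near-identical copies may share. None of 72 respiratory chain genes (list adjusted p = 0.0627; 4 genes at unadjusted p under 0.05 and 3 by limma-voom), 32 initiation factors (0.31; 4 and 1), 14 other TOP mRNAs (0.898; 1 and 0), 8 mitochondrially encoded genes (0.711; 0 and 2) or 14 integrated stress genes (0.792; 3 and 2) was called by limma. Of 21 antioxidant genes Prdx6 (-0.51) fell (0.711), and of 11 immediate early genes Egr1 (0.44) rose just inside the threshold, in a list with a positive test but a negative median and mean (0.625). Without knockout 1 or knockout 3 none of the single-gene calls in this paragraph was kept. Without wild type 2 those of Tfeb and Syt1 were, and without wild type 3 those of Syt1, Slc17a6 and Rpl29.

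Footprints count ribosomes over all mRNA copies of a gene and so also follow its RNA level. In footprints, 29 of 12447 genes were called, 16 higher and 13 lower in the knockout. Their groups lay apart, which a call all but requires, as in 39.6% of the genes not called and in 33.3% by chance. Spon2 rose from 0.806 ± 0.106 to 232.2 ± 42.2 RPKM (SE of the log2 fold change 0.18, adjusted p = 0.00088) and Fabp7 from 40.7 ± 4.25 to 743.7 ± 93.4 (4.16, SE 0.15, adjusted p = 0.00262). C2cd4b (4.91), Slc5a8 (3.82), Fam124b (2.94), the transcription factor gene Sox3 (2.91), Cdkn1a (2.37), Il17rd (2.33) and Npas2 (2.27) rose as well, and Cnksr1 was listed at 0 in the wild type and at 13.5 ± 3.10 RPKM in the knockout (adjusted p = 0.0248). Etnppl fell from 62.2 ± 0.626 to 9.55 ± 0.511 RPKM (-2.58, SE 0.14, adjusted p = 0.014), and the other large decreases were in Phospho1 (-3.06), Nr1d2 (-2.65), Ciart (-2.40), Tdo2 (-2.33), the ribosomal protein gene Rpl13a (-2.32), Nat8f5 (-2.26), Sulf1 (-2.12), Dbp (-2.03) and Plin4 (-1.99). In all, 1294 genes had an unadjusted p under 0.05, and limma-voom called 210. Of the 29 genes called by limma, 26 had recovered reads, and 22 of these were among the 210. The count was 1 without knockout 1 and 1 without knockout 3 (Spon2), 6 without wild type 2 and 5 without wild type 3, and it was 17 with a pseudocount of 0.1, 1 with no filter, 57 among genes with a mean read count of at least 100 and 315 with all libraries in one fit.

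Of the 15 E-box clock genes Nr1d2, Ciart, Dbp and Tef (-1.16) were called lower in footprints, and 14 passed over the list alone. Nr1d1 (-2.55, adjusted p = 0.0788), Per3 (-2.36, 0.0794) and Cry1 (0.93, 0.0918) were not called. The list was called lower (camera adjusted p = 6.14e-15, and 0.477 with an estimated correlation), and it was so without each animal, while none of the 4 single calls was. Choroid plexus markers were called higher (adjusted p = 1.09e-08; 0 of 11 genes called by limma, 9 at unadjusted p under 0.05, 5 over the list alone, 8 by limma-voom), with Ttr at 38433 and 39594 RPKM in the knockout, 16459 in wild type 2 and 522.1 in wild type 3. Oligodendrocyte markers were called lower (1.16e-04; 0 of 17 called, 7 at unadjusted p under 0.05, 4 over the list alone, 4 by limma-voom), with the myelin gene Mal at -0.61. Granule neuron markers were called higher (0.00118; 0 of 16 called, 6 at unadjusted p under 0.05, 2 by limma-voom), with Cbln3 at 0.47, and microglia markers lower (0.00457; 0 of 13, 5 and 0). Brainstem genes (0.00967; 0 of 7, 3 and 0), among them Hoxb5 with 69.5 RPKM in wild type 2 and 2.71 in wild type 3, and interneuron markers (0.0157; 0 of 14, 3 and 1) were called lower. With an estimated correlation the adjusted p of these lists was 0.718 for choroid plexus, oligodendrocyte, microglia and interneuron markers, 0.985 for granule and 0.729 for brainstem. By fry no list was called in footprints, with adjusted p = 0.0627 for the E-box clock genes. On the limma-voom fit 6 of the 7 lists were called in the same direction. The granule call was lost without knockout 3 (0.0625) or wild type 2 (0.203), the microglia call without knockout 1 (0.154), and the brainstem and interneuron calls without knockout 1 (0.0813 and 0.0809), knockout 3 (0.0515 and 0.0586) or wild type 2 (0.607 and 0.178). None of 45 mTORC1 pathway genes was called in footprints by limma or limma-voom (1 at unadjusted p under 0.05; list adjusted p = 0.876), and of 6 reactive glia genes none was by limma (2 at unadjusted p under 0.05, 1 by limma-voom; list adjusted p = 0.913).

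Genotype differences in footprints went along with those in total RNA. Across the 12089 genes tested in both, the fold changes had a Pearson correlation of 0.636, and 0.898 among the 500 genes called in total RNA, across genes that are not independent replicates. Of these 500 genes, 473 (94.6%) had the same direction in footprints, against 64.6% of the genes not called. All 26 genes called in both, 15 higher and 11 lower, had the same direction. Libraries of both kinds come from the same lysates, so that differences between animals enter both comparisons: across genes, the difference of wild type 2 and wild type 3 had a correlation of 0.259 between kinds, and that of knockout 1 and knockout 3 of -0.004. Without knockout 3 the correlation was 0.472.

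**Figure D4:**
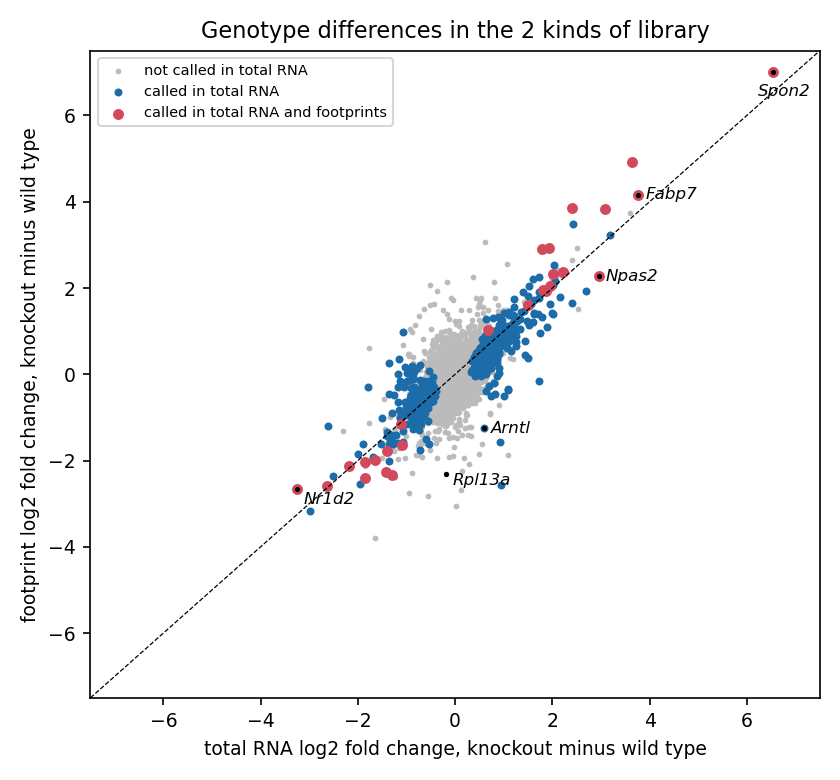
Log2 fold change, knockout minus wild type, in footprints against total RNA for the 12089 genes tested in both, with the dashed line marking equal changes. Red points are the 26 genes called in both and blue the other genes called in total RNA: Fabp7 lies at 3.76 and 4.16, and Arntl (0.59 and -1.25) and Rpl13a (-0.20 and -2.32) lie off the line.

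Translational efficiency, the footprints of a gene relative to its total RNA, addressed whether the knockout changes translation apart from RNA level. Of 12089 genes, 2 were called, both lower in the knockout: Arntl and Rpl13a (ENSMUSG00000074129, chromosome 7, 45125558 to 45128761). For Rpl13a the ratio was 0.0177 and 0.0116 in the knockout and 0.0760 and 0.0790 in the wild type (-2.12 log2 units, SE 0.19, adjusted p = 0.0367), with 18 and 10 footprint reads in the knockout and 87 and 67 in the wild type. Fewer than 10 genes passed, and those with the next smallest p that did not pass were Phospho1 (-3.08), Fam81b (-2.50), Sept2 (2.30), Rnasek (-2.80), Rpl23 (1.19), Col14a1 (-1.86), Gm35315 (-2.26) and Irak4 (-1.12), with adjusted p from 0.131 to 0.317. There were 550 genes with an unadjusted p under 0.05, and limma-voom called Arntl alone (-1.80, adjusted p = 0.00142). With the animal as a fixed block, which takes out differences shared by the libraries of one lysate, neither gene was called (Arntl adjusted p = 0.132, Rpl13a 0.18) and Phospho1 was (adjusted p = 0.0358). Without any one animal no gene was called.

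No gene list with a role in translation was called in efficiency. For the mTORC1 pathway 0 of 45 genes were called by limma and by limma-voom (1 at unadjusted p under 0.05; list adjusted p = 0.915), with Ulk1 at -0.47 and Eif4ebp2 at -0.39. Of 53 ribosomal protein genes Rpl13a alone was called (list adjusted p = 0.592). In this list 7 genes were at unadjusted p under 0.05, 2 passed over the list alone and 0 were called by limma-voom. Of 14 other TOP mRNAs 0 were called by either tool (1 at unadjusted p under 0.05; list adjusted p = 0.915). Camera with its preset correlation called 5 lists with no called member by limma or limma-voom and 0 to 3 members at an unadjusted p under 0.05. Genes recurrently mutated in autism (adjusted p = 0.0313, 24 of 34 negative), ion channels (0.0313, 21 of 24 negative), synapse genes (0.0442, 21 of 30 negative) and E-box clock genes (0.0442, 13 of 15 negative) were lower, and respiratory chain genes (0.0442, 47 of 70 positive) higher. Footprints of the autism, ion channel and synapse lists had medians near 0 (-0.02, -0.03 and -0.03, adjusted p = 0.777, 0.913 and 0.962), and their total RNA medians were positive (0.06, 0.11 and 0.11). With an estimated correlation adjusted p was 0.993 for each. Under median centring 2 of the 5 lists were called, both lower. With the animal as a block the autism, ion channel and synapse lists were called (adjusted p = 0.0374 each) and the other 2 were not. None of the 5 was called without knockout 1 (adjusted p 0.297 to 0.83) or without wild type 3 (0.847 each). Without knockout 3 the autism (0.0532), ion channel (0.0609) and synapse lists (0.331) were lost, and without wild type 2 the E-box list was (0.0927), while choroid plexus markers were called higher (0.00126).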

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

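Of the tests in this part, that of annotated copies of Rpl13a and that of genes outside the choroid plexus list were set before their results were seen, and the others were chosen after.

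Arntl differed between the kinds of library, with an interaction of -1.841 log2 units (total RNA 0.59, footprints -1.25). Scaling of the libraries is argued against, since it would move all genes together and their median interaction was -0.018. Under 4 other scalings the difference nearest to 0 was -1.801. Their medians over all genes lay between -0.018 and 0.011, so they could hardly have moved it further. Genotype labels exchanged in one kind of library are argued against by the E-box clock genes, since all 13 of the 13 called in total RNA had the same sign in footprints. Exchanged kinds of library are argued against by correlations across genes, of at least 0.981 within a kind and at most 0.922 between kinds. As a hypothesis, the pattern may come from a transcript of the targeted allele that is made but little translated, with more RNA where the repressors Nr1d1 (-1.96) and Nr1d2 (-3.26) have fallen, which stays untested here because values per exon were not analysed.

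Rpl13a differed between the kinds of library as well, with an interaction of -2.123 log2 units (total RNA -0.20, adjusted p = 0.283; footprints -2.32, 3.39 RPKM in the knockout) that moves with the pseudocount, to -2.40 at 0.1 and -1.43 at 5 (adjusted p = 0.112). Counting error is argued against: 28 of its 182 footprint reads, 15.4%, came from the knockout, with an exact 95% Clopper-Pearson interval of 10.5% to 21.5% that covers counting error only, and the knockout libraries held 52.0% of all footprint reads. Reads shared with copies of the gene stay open, since the annotation names 1 pseudogene after Rpl13a, further copies can carry other names, and so few footprint reads can follow small differences in how reads are placed. Limma-voom, which weighs this depth, gave adjusted p = 0.199 in footprints (SE 0.82) and 0.981 for efficiency. An effect of genotype on the gene could also give this difference and stays untested.

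Choroid plexus genes were higher in knockout total RNA, by a median of 2.11 log2 units over 9 markers, and the animals of the wild type differed from each other by a median of 1.606, with 8 of 9 higher in wild type 2. An unequal share of choroid plexus in the dissected tissue and an effect of genotype on this tissue cannot be told apart with 2 animals per group, since the animals of one genotype differed almost as much as the genotypes. Whether that share also raises other genes stays open. The share read from Ttr predicts at least 50% of the difference in 13 of the 313 other genes called higher (4.2%), among them Cldn5, but each prediction is a multiple of the gene's own difference between the wild-type animals, and a call needs that difference to be small, so a low count excludes nothing. Enpp2, which oligodendrocytes express too, was at 8537 and 9428 RPKM in the knockout, 5429 in wild type 2 and 2004 in wild type 3.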

How the results depend on the processing

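The limma-voom fits were chosen after seeing the data, and all other settings before. With 1 library left out, the lone library of a group is assumed to vary like those of the other group. Of the called genes under the rule for naming genes (65 in total RNA, 21 in footprints, 2 in translational efficiency), none changed direction in a setting that tested it. The called genes named only under other observations were part of these fits, and their values under each setting were not tabulated. Genes changed in total RNA (519) numbered 26 with no filter, 217 with all libraries in one fit, 798 with a mean read count of at least 100, 117 to 563 without 1 library, and 1684 (816 higher, 868 lower) and 1500 (940 higher, 560 lower) by limma-voom with total and median-ratio library sizes. The other 6 settings gave 350 to 591. Genes changed in footprints (29) numbered 17 with a pseudocount of 0.1, 1 with no filter, 57 with a mean read count of at least 100, 315 with all libraries in one fit, 1 to 6 without 1 library, and 210 and 212 by limma-voom. The cause of the differences between settings was not tested, except that fewer libraries leave fewer degrees of freedom.

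Genes changed in translational efficiency (2) numbered 5 with a pseudocount of 0.1 (Arntl, Rpl13a, Cnksr1, Gm35315, Rnasek), 1 with a pseudocount of 5 (Arntl), 4 with no filter (among them Gm42957, Slfnl1 and Npy4r), 0 with quantile normalization, 0 without a variance trend, 0 to 0 without 1 animal, and 1 and 1 by limma-voom (Arntl). With the animal as a fixed block the count was 1 (Phospho1), and as a random block 2. Gene lists changed in total RNA (7) numbered 0 with an estimated correlation, 3 by fry, 8 to 11 without 1 library and 13 by limma-voom. Gene lists changed in footprints (7) numbered 0 with an estimated correlation, 0 by fry and 4 to 10 without 1 library. Gene lists changed in translational efficiency (5) numbered 0 with an estimated correlation, 0 by fry, 2 under median centring, 3 with the animal as a fixed block and 0 to 5 without 1 animal. The correlation of fold changes (0.636) was 0.705 with a filter at a mean of 5 and 0.472 to 0.601 without 1 animal.

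No paired analysis was possible for total RNA or footprints, genes or lists, because the genotypes share only replicate number 3. The alternative with DESeq2 had been planned only for files that hold counts and was not run, and on the recovered reads limma-voom was run in its place. Genes with few reads per RPKM unit are judged at a lower depth than their RPKM implies, and with 2 animals per group a call rests on the spread that limma borrows from other genes.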

Other observations

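Genes of the basement membrane, the matrix sheet under epithelia and around vessels, were among those that rose in knockout total RNA: of 34 tested, 8 rose and 0 fell. The collagen genes Col4a2 (1.94) and Col4a1 (1.73), Frem2 (1.80), the laminin genes Lama5 (1.20) and Lamb1 (0.66), Npnt (1.02), Nid2 (0.90) and Sparc (0.80) were called, and 13 passed over the list alone. In the same libraries choroid plexus markers were higher (median 2.11, with wild type 3 apart) and the endothelial gene Cldn5 rose (0.84). Of the 14 endothelial and mural markers tested, however, 8 had a negative fold change (median -0.14, camera adjusted p = 0.711). An unequal share of choroid plexus or vessels in the tissue is not excluded for the basement membrane genes. In footprints 1 of 33 was called, Frem2 (1.96), and 4 passed over the list alone, with a median of 0.14 over the list against 0.19 in total RNA. Col4a1 (1.92), Col4a2 (1.64) and Lama5 (1.37) had footprint fold changes near those in total RNA and were not called. Of 28 interferon-induced genes, which act against viruses, 5 fell and 0 rose, among them Ifit3b (-2.98), Ifit3 (-1.40), Trim30a (-1.14) and Trim30d (-1.07). Microglia markers were lower in the same libraries (median -0.37, 12 of 12 negative, list adjusted p = 1.27e-04, and 0.593 with an estimated correlation). In footprints none of 27 interferon-induced genes was called by limma (2 over the list alone), with a median of -0.01 against -0.16 in total RNA. Ifit3b (-3.18, adjusted p = 0.0671) and Ifit3 (-1.34) had footprint fold changes near those in total RNA, and Trim30a had a positive one (0.35, SE 0.62).

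All tests in this part were chosen after the results were seen, and both lists were written with the called genes in view and include some of them, so that their p cannot show that the groups move together. As hypotheses, basement membrane genes may rise together (Fisher's exact two-sided p = 1.36e-06, odds ratio 12.4; camera p = 0.000722, and 0.144 with an estimated correlation) and interferon-induced genes may fall together (Fisher's exact two-sided p = 7.43e-05, odds ratio 13.6; camera p = 0.00221, and 0.0747 with an estimated correlation). Trim30a and Trim30d lie within 10 Mb of Arntl, where variants from the strain in which the allele was made could remain next to it. Within that distance 8 of 109 genes were called in total RNA (7.3%), against 4.05% elsewhere, a difference that did not pass (Fisher's exact two-sided p = 0.0878, odds ratio 1.87). The labels give a C57BL/6 background for all samples, and linked variants and an effect of genotype cannot be told apart for these 8 genes. They include Wee1 (-0.80), which is also counted among the E-box clock genes that fell. All 4 animals expressed the Y-linked gene Ddx3y, at 901.8 to 1112 RPKM in total RNA.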
